A study of Homo sapiens with 2 samples.

How the data were processed

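Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the binding of GATA2, a zinc-finger transcription factor of the GATA family, in LNCaP, an established androgen-responsive human prostate cancer cell line. Per the labels' protocols, the cells were kept in RPMI with 10% serum and moved to medium with 5% charcoal-treated serum, which is depleted of steroid hormones, 3 days before the assay. Sonicated chromatin was enriched with an antibody against GATA2, and libraries were amplified for 16 cycles, selected at about 225 bp including adapters and read on an Illumina Genome Analyzer. The labels give 1 group of 2 replicate ChIP samples, and no input, untreated or other control group among the samples used here.

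The data analysed were 1 deposited list of peaks for the whole series. Reads were aligned with Bowtie to hg19, per the submitters' processing notes, and peaks were called with MACS, per the peak names in the file. The versions of both tools, the use of a control library, the treatment of duplicate reads and whether the replicates were pooled before peak calling are not given in the sources used here. Each line of the deposited list holds a chromosome, a start, an end and a score, the authors' own value from the peak caller. The score has no stated unit. Its deposited values start just above 80, at 80.01, and end at 3100, a value shared by 4 peaks, which is the pattern of a scaled negative logarithm of the peak p-value with a threshold and a ceiling. The name given to the deposited list also carries a tag of the caller's p-value threshold that fits this lower limit. The scale itself is not stated in the sources used here, so it was treated as a score that ranks peaks and not as a measure of binding strength. It was used only to rank, filter and describe peaks within this list. No column belongs to a single replicate, so no value here has a replicate error, no p-value was computed, and no replicate could be left out. The list gives no read counts, so the sequencing depth behind each peak is unknown.

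Start positions were converted to 1-based coordinates and peak centres were taken as the midpoint. Peak-free stretches longer than 2.5 Mb between neighbouring peaks were located, and the usable length of a chromosome was the length from its first to its last peak less these stretches. That minimum was chosen after the lengths had been seen, since no stretch fell between 2.27 and 3.00 Mb. Peaks per Mb were computed on the usable length, with 95% intervals from 2000 resamples of 1 Mb bins. For the density beside long stretches relative to that elsewhere, the stretches were resampled instead. Medians have exact binomial 95% intervals from order statistics, and shares have Wilson 95% intervals. These intervals cover counting over peaks, bins or stretches only, and peaks are not replicates.

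Spacing was compared with 1000 random placements of the same number of peaks on the usable length of each chromosome, and with 1000 placements in which every peak stayed within its own 1 Mb bin. Both counted peaks whose nearest neighbouring centre lay within 10 kb, and runs of at least 5 peaks in which successive centres were no more than 12.5 kb apart. The calculation over whole chromosomes was checked on simulated lists of 36797 peaks, drawn by the same uniform placement. This check used fewer placements per list than the 1000 used for the real list. Without added companions, 23.0% of simulated peaks had a neighbour within 10 kb, against a mean of 23.1% over the placements. With 2000 companions added close by the share was 30.6%, above the highest placement at 23.7%. Because the simulated lists were uniform, this checks the calculation and not whether uniform placement suits the real list. Placement within 1 Mb bins was not checked in this way. For the comparison of X with autosomes, a simulated list of 27685 peaks with a true ratio of 0.5 returned 0.50 (95% interval 0.47 to 0.53). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

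The rules for what is named were fixed before the data were examined: the 10 peaks with the highest score (ties broken by width, then genome order) and the 10 bins of 1 Mb with the most peaks, by position. Alternatives fixed at the same time were the better-scoring 50% and best-scoring 10% of peaks, merging of peaks less than 500 bp apart, and leaving out chromosome Y. The comparisons between chromosomes, the spacing comparisons and the treatment of long peak-free stretches were added afterwards. No genome sequence or gene annotation of hg19 was used here, so distance to transcription start sites, location in exons and introns, the content of GATA and other motifs, and lists of prostate, androgen-responsive and other genes were not analysed. A table of gene names from GRCh38 was at hand and was not used, since positions from different builds cannot be joined.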

Results

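GATA2 binding was profiled by ChIP-seq in 2 replicate samples of LNCaP prostate cancer cells held in steroid-depleted medium, and the question set by the design was where in the genome GATA2 binds. For the series there was 1 deposited list, with no value per replicate and no statement of how each replicate entered it, so the spread between replicates and the read depth behind each peak are unknown. The list held 36797 GATA2 peaks on 24 chromosomes of hg19, none overlapping another. Together they covered 11.4 Mb, or 0.397% of the 2870 Mb of usable chromosome length, at a mean of 12.8 peaks per Mb. Peaks had a median width of 293 bp (95% interval 291 to 294 bp), and the middle 50% of them measured 217 to 372 bp. The authors' peak score ran from 80.01 to 3100, with a median of 212.2 (95% interval 210.2 to 215.0) and an upper quartile of 396.8. Peaks scoring under 100 made up 11.9% of the list. Wider peaks scored higher (Spearman's rho 0.83 across peaks, which are not independent replicates), and the median width went from 160 bp in the lowest-scoring 10% to 455 bp in the best-scoring 10%.

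GATA2 peaks were spread over every autosome, with the lowest density on chromosome 19 and the highest on chromosome 21. Chromosome 19, known as the most gene-dense human chromosome, held 483 peaks, or 8.64 per Mb (95% interval 7.55 to 9.92). Chromosome 21 held 574 peaks, or 16.2 per Mb (95% interval 13.4 to 19.2), and chromosome 1 held 3508 peaks, or 15.4 per Mb (95% interval 14.5 to 16.3). The median over the 22 autosomes was 13.2 peaks per Mb. The density on chromosome 19 was 0.65 times that of the other 21 autosomes combined (95% interval 0.56 to 0.76). Its peaks also had the lowest autosomal median score, at 172.4 (95% interval 160.5 to 192.1), against medians of 197.8 to 223.7 on the other autosomes.

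Chromosome X carried fewer and lower-scoring GATA2 peaks than the autosomes. It held 984 peaks, or 6.48 per Mb (95% interval 5.80 to 7.20), which was 0.49 times the autosomal density of 13.2 per Mb (95% interval of the ratio 0.44 to 0.55). The median score on X was 183.5 (95% interval 170.8 to 193.8), and that on the autosomes was 214.2 (95% interval 211.4 to 216.4). The deficit was larger among higher-scoring peaks. The X to autosome ratio was 0.42 (95% interval 0.37 to 0.47) for the better-scoring 50% of the list and 0.20 (95% interval 0.14 to 0.27) for the best-scoring 10%. Chromosome Y held 325 peaks, or 13.1 per Mb, with a 95% interval of 7.24 to 22.2 that includes the autosomal density. Of these, 101 lay in a single 1 Mb bin, and without the peaks within 1 Mb of a long peak-free stretch the density on Y was 7.63 per Mb, or 0.59 times the autosomal density (95% interval 0.43 to 0.76). With all peaks the Y to autosome ratio was 0.99 (95% interval 0.54 to 1.67). It was 0.69 (95% interval 0.44 to 1.01) for the better-scoring 50% and 0.41 (95% interval 0.20 to 0.67) for the best-scoring 10%.

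**Figure D1:**
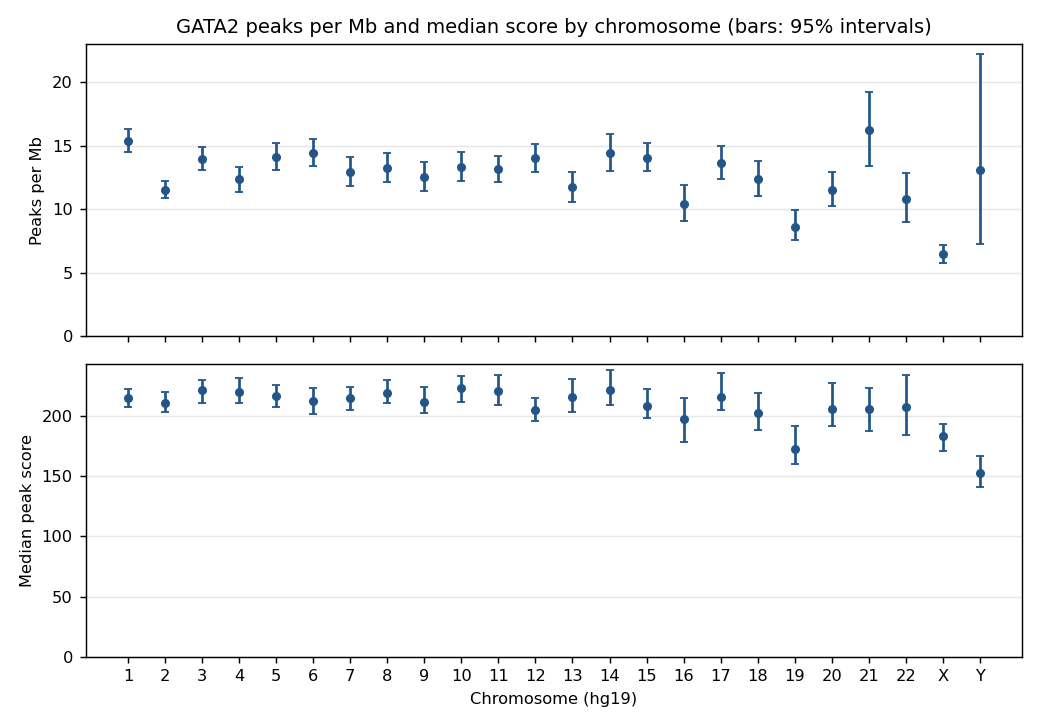
Peaks per Mb of usable length (top) and median peak score (bottom) for each hg19 chromosome; points are values and bars are 95% intervals over 1 Mb bins (top) or peaks (bottom). Chromosomes 19 and X have the fewest peaks per Mb, 8.64 and 6.48, and the interval for Y is wide, from 7.24 to 22.2.

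At the megabase scale the peaks were unevenly spread. The 2821 whole bins of 1 Mb held a mean of 12.6 peaks (SD 6.57 across bins), with a variance 3.42 times the mean, and 10 of them held none. The densest bin was chromosome Y from 13 to 14 Mb, with 101 peaks of median score 123.8 and median width 164 bp. Chromosome 7 from 61 to 62 Mb followed with 68 peaks of median score 112.8 and median width 138 bp. Both bins touched a peak-free stretch longer than 2.5 Mb, and their peaks were narrower and lower-scoring than the list as a whole. The bin on chromosome 21 from 10 to 11 Mb held 38 peaks with a median score of 138.5, and 32 of these lay within 1 Mb of such a stretch. Chromosome 16 from 33 to 34 Mb held 37 peaks with a median score of 146.5, with the nearest long stretch 1.29 Mb away.

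The other 6 of the 10 densest bins lay far from long peak-free stretches. Chromosome 14 from 30 to 31 Mb held 44 GATA2 peaks with a median width of 337.5 bp and a median score of 198.4 (95% interval 153.9 to 279.4), an interval that includes the median of the whole list. Its highest-scoring peak, at positions 30364678 to 30366854, was 2177 bp wide and scored 903.8. A run of 3 adjoining bins on chromosome 6, from 26 to 29 Mb, held 127 peaks with a median score of 168.2 (95% interval 139.7 to 197.2). The highest-scoring peak there, at 27204131 to 27204865, scored 1103. On chromosome 5, from 69 to 71 Mb, 2 adjoining bins held 75 peaks with a median score of 308.5 (95% interval 148.8 to 380.8) and a median width of 355 bp. Among the 34 bins with at least 31 peaks, the 99th percentile, 2 more adjoining pairs lay on chromosome 3. The pair from 174 to 176 Mb held 67 peaks with a median score of 215.4, and the pair from 177 to 179 Mb held 64 peaks with a median score of 212.4.

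**Figure D2:**
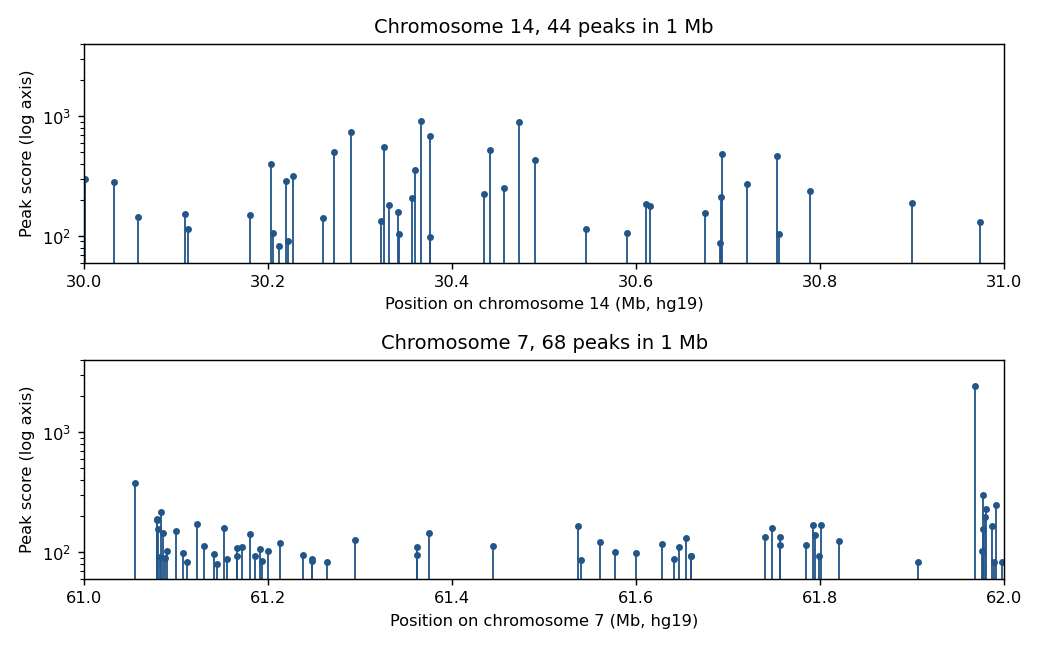
Position (Mb, hg19) and score (log axis) of each GATA2 peak in a dense bin of chromosome 14 (top, 44 peaks) and of chromosome 7 (bottom, 68 peaks); each stem is 1 peak. Peaks on chromosome 14 reach scores up to 903.8, whereas those on chromosome 7 have a median of 112.8 with 1 peak at 2452.

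GATA2 peaks lay closer together than randomly placed peaks. A neighbouring peak centre lay within 10 kb for 12227 peaks, or 33.2% (Wilson 95% interval 32.8% to 33.7%). In 1000 random placements on the same chromosomes the share averaged 23.1% and never exceeded 24.1%, so the observed share was 1.44 times the random one. The median distance to the nearest peak was 19.1 kb, against 26.6 kb for placed peaks. Runs of at least 5 peaks with successive centres no more than 12.5 kb apart numbered 180, against a mean of 17.7 and a highest value of 34 in the placements over whole chromosomes. With each peak placed within its own 1 Mb bin the mean was 66.0 runs and the highest value 87, so the observed number was 2.73 times the placed mean. The share of peaks with a neighbour within 10 kb averaged 26.3% in those placements, and the observed share was 1.26 times that. Of the 180 runs, 55 lay within 1 Mb of a long peak-free stretch. Without the peaks there 125 runs remained, against a mean of 16.3 over whole chromosomes. Placement within 1 Mb bins was not run without those peaks. The 1 Mb limit does not separate all similar runs. For example, a run of 16 peaks on chromosome 9 (66783257 to 66843924), with a median score of 137.9, lay not far beyond it. The longest run away from those stretches, by number of peaks, held 33 peaks over 68.4 kb of chromosome 2 (132975618 to 133044024), with a median score of 136.2. Median scores of the 125 runs ranged from 93.0 to 580.8 with a middle value of 197.6, and 69 of them lay below 215.7, the median of all peaks away from long stretches.

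**Figure D3:**
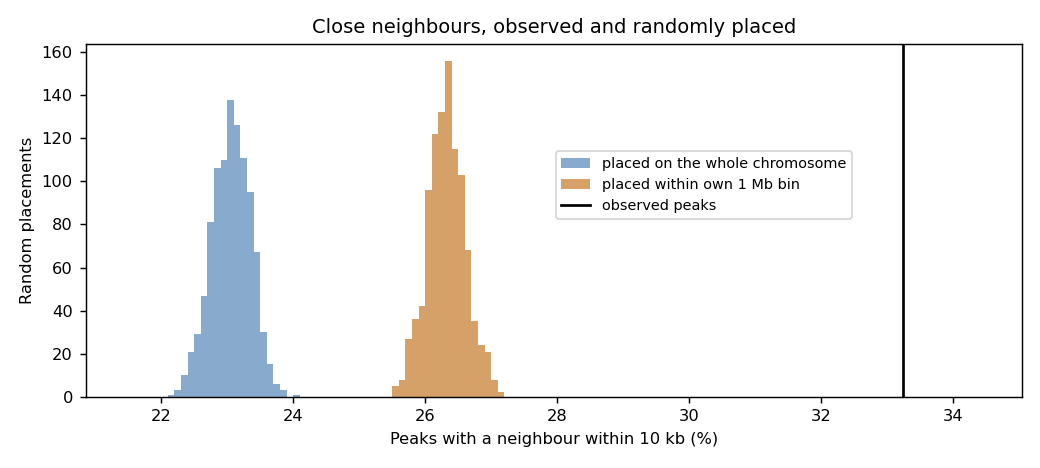
Share of peaks with a neighbouring centre within 10 kb (x axis, percent) in 1000 random placements over whole chromosomes (blue) and 1000 within each peak's own 1 Mb bin (orange); the y axis counts placements and the black line is the observed share. The observed 33.2% lies above both sets, whose highest values were 24.1% and 27.2%.

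The 10 highest-scoring peaks lay on 10 different chromosomes. The highest score in the list, 3100, was shared by 4 peaks and may be a ceiling of the score, so these 4 cannot be ranked among themselves by it. These were on chromosome 3 (96336025 to 96337429, 1405 bp wide), chromosome 1 (121484046 to 121485438, 1393 bp), chromosome 17 (51183090 to 51183818, 729 bp) and chromosome 2 (88124366 to 88124882, 517 bp). The peak on chromosome 13 (110076468 to 110076781) was 314 bp wide and scored 3051. The peak on chromosome X (125606306 to 125607269) was 964 bp wide and scored 2884. The peak on chromosome 18 (45379613 to 45379814) was 202 bp wide and scored 2726, and that on chromosome 4 (12641854 to 12642266) was 413 bp wide and scored 2703. Chromosome 14 (32953332 to 32954395) held a peak of 1064 bp with a score of 2670, and chromosome 7 (61967154 to 61969733) held a peak of 2580 bp with a score of 2452. In width, 7 of these 10 fell outside the range of 354 to 757 bp that holds the central 90% of the best-scoring 10% of peaks. The peaks on chromosomes 1 and 7 lay within 1 Mb of a long peak-free stretch, and the peak on chromosome 1 directly adjoined it. Some of these positions may lie in regions of hg19 known for anomalously high signal in many ChIP-seq experiments or for nuclear copies of mitochondrial DNA. No list of such regions was applied here, so these 10 peaks are the highest-scoring entries of the list and are not established as the strongest GATA2 sites. Which genes or sequence elements lie at these positions was not analysed here.

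**Figure D4:**
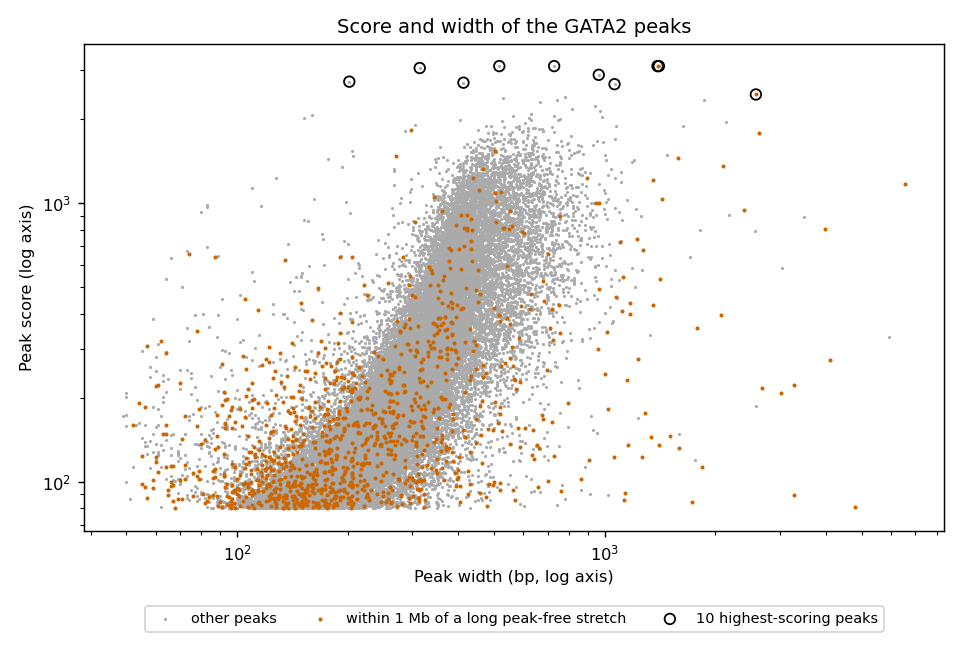
Peak score against peak width (bp), both on log axes, for all 36797 peaks; orange points lie within 1 Mb of a long peak-free stretch and black circles mark the 10 highest-scoring peaks. Most peaks form 1 rising band, and 7 of the 10 circled peaks lie outside the width range of 354 to 757 bp that holds the central 90% of the best-scoring 10%.

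Between neighbouring peaks, 22 stretches longer than 2.5 Mb held no GATA2 peak, on 20 chromosomes. In 18 cases the length was between 3.00 and 3.30 Mb. The longest of all 22 were 30.2 Mb on chromosome Y (28805873 to 58972824), 21.1 Mb on chromosome 1 (121485439 to 142535724), 18.4 Mb on chromosome 9 (47229006 to 65594559) and 11.2 Mb on chromosome 16 (35285566 to 46430794). Chromosome 8 had a stretch at 43838892 to 46838884 and another, of 3.03 Mb, at 137617331 to 140645507. Chromosomes 13, 14, 15 and 22 had no such stretch between peaks, but their first peaks began between 16.1 and 20.0 Mb from the chromosome start. Those peak-free starts were not counted as stretches, and peaks beside them were counted with the rest of the list. The next longest peak-free regions between neighbouring peaks were 2.27 Mb on chromosome 8 (3454227 to 5723428), 2.23 Mb on chromosome 16 (6655514 to 8885753) and 2.11 Mb on chromosome 4 (179133709 to 181243314). The 1128 peaks within 1 Mb of a long stretch, 3.07% of the list, had a median score of 139.0 (95% interval 132.5 to 145.2), against 215.7 (95% interval 213.3 to 218.0) for all others. They numbered 26.0 per Mb, against 12.6 per Mb elsewhere. Outside chromosomes 7 and Y the density beside the 19 stretches was 1.81 times that elsewhere (95% interval 1.51 to 2.11), but 1.04 times (95% interval 0.84 to 1.29) for the better-scoring 50% of peaks and 0.86 times (95% interval 0.59 to 1.10) for the best-scoring 10%, so the excess lay among low-scoring peaks.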

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

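The density of peaks beside long peak-free stretches outside chromosomes 7 and Y, 1.81 times that elsewhere with all peaks, was 1.04 times for the better-scoring 50% and fell below 1, to 0.86, for the best-scoring 10%, and the cause was not tested. The fold over random placement and the X and 19 ratios kept their direction. The 36797 peaks became 18399 with the better-scoring 50% and 3680 with the best-scoring 10%, by construction. The share of peaks with a neighbour within 10 kb was 17.2% and 4.54% in those subsets, 29.7% after peaks under 500 bp apart were merged, 32.1% without peaks within 1 Mb of a long peak-free stretch and 32.7% without the 10 densest bins. The fold over random placement, 1.44 with all peaks, was 1.38 for the better-scoring 50%, 1.65 for the best-scoring 10%, 1.32 after merging, 1.41 without peaks beside long stretches, 1.49 with placement over the whole length between first and last peak, and 1.26 with placement within 1 Mb bins. The X to autosome ratio of 0.49 became 0.42 for the better-scoring 50% and 0.20 for the best-scoring 10%. The ratio of chromosome 19 to other autosomes, 0.65 with all peaks, was 0.53 and 0.61 in those subsets, and the cause was not tested. Leaving out chromosome Y cannot move the ratios for X and 19 and was not counted for them. Of the other 46 alternative values, 21 stayed within the 95% interval of the value reported, or within 1.5 times it for the count of peaks. The settings on long stretches, the 10 densest bins, whole length and 1 Mb placement were chosen after seeing the data. Alternatives that need a genome or annotation (promoter windows, motif windows and strings, gene-list windows and matching) were not run, nor was leaving out a replicate, since the list holds no value per replicate. No paired analysis was possible because there is 1 group and the list carries no replicate numbers. Depth is unknown, so a region without a peak cannot be read as unbound.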

Other observations

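The first peaks of 5 chromosomes began between positions 9997 and 10005. They were on chromosomes 1, 4, 5, 7 and 18, and that on chromosome 5 extended to position 11814 with a score of 802.6. Of the 5 widest peaks, 4 lay within 100 kb of a long peak-free stretch. The widest, 6580 bp on chromosome 10 (42383244 to 42389823), scored 1171. The second, 5941 bp on chromosome 1 (564415 to 570355), scored 329.8 and lay far from any such stretch. No list of regions with anomalous signal was applied to these first peaks or to the widest peaks either. Neither set is therefore established as GATA2 sites. Peaks with a neighbour within 1 kb had a median score of 151.2 (95% interval 146.9 to 155.8), and those whose nearest neighbour was 10 to 100 kb away had a median of 223.0 (95% interval 219.8 to 226.3). The median was 213.0 (95% interval 208.7 to 217.0) for a nearest neighbour 1 to 10 kb away and 198.9 (95% interval 191.8 to 206.2) for one over 100 kb away, so the score did not rise steadily with isolation. Neighbouring peaks 1 to 10 kb apart had only weakly related scores (Spearman's rho 0.065 across 5895 pairs, against at most 0.032 in 200 shuffles). Without peaks beside long stretches, rho was 0.026 for these pairs, within the range of the shuffles, and 0.031 for pairs over 100 kb apart, above the highest shuffle at 0.026.

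Of the tests below, those on the dense bins and on chromosome X were chosen after the result was seen, and those on spacing were set before the placements were run. Each technical source tested was taken alone, and none by itself, as far as its test reached, accounted for the whole excess of close neighbours. The sources were not removed together, so their joint share is unknown. Splitting of 1 enriched region narrower than 2 kb into several calls would give an excess below 2 kb only. Yet neighbours 2 to 10 kb apart were 1.44 times as frequent as in random placements over whole chromosomes, above the highest of 1000. Against placements within 1 Mb bins that fold was 1.24, again above the highest placement. Over whole chromosomes without the peaks beside long stretches it was 1.40, also above the highest placement. The widest single peak measured 6580 bp, and splitting of regions wider than 2 kb could give such neighbours too. Splitting of such wide regions was not tested. Without the peaks beside long peak-free stretches the fold within 10 kb was 1.41. The 1 Mb limit leaves in low-scoring runs farther away, such as that of 33 peaks on chromosome 2. Repeat sequence elsewhere was therefore not addressed. With every peak kept in its own 1 Mb bin the fold within 10 kb was 1.26. Megabase differences in copy number or mappability therefore account for part of the excess at most. Local differences in mappability below 1 Mb were not tested, and no biological explanation was tested, since the design holds 1 group. Grouping of GATA2 sites within regulatory regions is a hypothesis that may be followed up with an hg19 annotation.

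The dense bins on chromosomes Y and 7 adjoin long peak-free stretches, and hg19 is known to represent centromeres by stretches of undetermined bases. A candidate explanation is repeat sequence at the edges of such gaps. Over all 22 stretches the median width of peaks within 1 Mb was 0.94 times that of other peaks of similar score, but that figure includes the bins in which the pattern was noticed. On the 19 stretches outside chromosomes 7 and Y, tested after the first ratio was seen, it was 0.96 (95% interval 0.94 to 1.00). That interval is over pooled peaks and does not cover the spread between stretches. With those on 7 and Y included, only 15 of 22 stretches had a ratio below 1, and ratios ran from 0.747 to 1.305. Narrowing therefore does not decide the matter, and the explanation stays open without a repeat annotation. Widths departed both ways. On the same 19 stretches, 40.9% of peaks (Wilson 95% interval 37.6% to 44.2%) lay outside the central 90% of widths of other peaks of similar score, 23.9% below it and 16.9% above it, against 9.92% of the others in all. Over all 22 stretches the share was 43.7%. A second candidate is gain of copies of an ordinary region. On the same 19 stretches, peaks per Mb within 1 Mb were 1.81 times those elsewhere (95% interval 1.51 to 2.11) for all peaks, 1.04 times (95% interval 0.84 to 1.29) for the better-scoring 50% and 0.86 times (95% interval 0.59 to 1.10) for the best-scoring 10%. Gain in regions otherwise like the rest would raise all of these. The last 2 intervals include 1 and lie below the interval for all peaks. To set gain aside, the ratio for the best-scoring 10% had to lie below 1 by more than its interval. It did not, and the density of these regions without gain is unknown, so the test cannot tell whether gain contributes. Peaks beside the stretches on chromosomes 7 and Y were left out of it.

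Chromosome X had 0.49 times the autosomal density of peaks. Fewer sites with unchanged scores would keep that ratio at any score threshold, whereas it was 0.42 for the better-scoring 50% and 0.20 for the best-scoring 10%, the latter with a 95% interval of 0.14 to 0.27 that lies below the interval of 0.44 to 0.55 for all peaks. What lowers the scores stays open, and fewer copies of X than of autosomes in these cells, lower mappability and weaker binding could not be separated, because the list holds no background coverage.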
